A study of Mus musculus with 2 samples.

How the data were processed

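Nuclei were prepared from sorted CD4+CD44+CD62L- effector T cells of mice 26 to 33 weeks old, with colon and small intestine pooled, and joint RNA and accessibility libraries were made with the 10x Multiome kit, aiming at 5000 nuclei per library, per the labels' protocols. cDNA was amplified with 7 cycles and libraries with 15. The control group is the library from Zfp362flox/flox mice and the knockout group the library from CD4creZfp362flox/flox mice, by the genotype given in the labels. The design text names 7 mice without saying whether this is per genotype. With 1 library per genotype, animals cannot be told apart and no test across samples exists.

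The deposited matrices hold whole-number counts per barcode that the authors produced with Cell Ranger ARC 2.0.1, per the file headers, on the mm10 build, per the submitters' processing notes. They have 32285 gene rows, whose values are raw UMI counts, and 83851 (control) and 85738 (knockout) peak rows called separately in each library. Of the peak values, 91.7% and 90.7% were even, so they look like counts of transposase insertion ends, of which each fragment has a pair. Peak values are therefore given as counts, and their intervals were computed on fragments, taken per nucleus and peak as the count divided by 2 and rounded up. Filters applied before deposit, other than calling of barcodes, are not given in the sources used here. Median depths per barcode were 1996 and 2270 UMIs, 1088 and 1165 genes, and 6546 and 9785 peak counts.

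Nuclei with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 47 control and 45 knockout barcodes. Doublets were called with scrublet (scanpy 1.11.5, expected rate 0.04), which marked 1 nucleus per library (0.0239% and 0.0426%). The caller was therefore taken not to have worked, and the marked nuclei were kept. Counts were scaled to 10000 UMIs per nucleus and log-transformed, and both libraries were clustered together without batch correction on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0). Zfp362, antigen receptor segments, mitochondrial and sex-linked genes were left out of the variable genes. A first clustering with UMAP edge weights was looked at. The weights were then changed to Jaccard weights, so that cluster labels do not depend on the processor, and the first weights became an added alternative.

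Clusters were named from markers fixed before the data were examined, while the thresholds of naming, the CD3-low rule, the mixed rule and the size rule were set after the data had been seen. A name needed at least 3 of its markers at a log2 ratio of at least 0.8 over all other nuclei, each with at least 5 UMIs, and no more markers of another T-cell class than of its own among its top 10 genes. Clusters whose Cd3 level was under 0.3333 of the median over clusters were kept out of the T lineage, and those of them with ILC markers form the CD3-low population. Unnamed T-lineage clusters whose median depth was more than 2 times that of all nuclei are the mixed high-UMI clusters. Class sizes were compared between libraries only where the median log2 ratio of the leading genes was under 0.5 in size. These names were rebuilt from the data, as no annotation of cells was used here.

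For each population, raw UMI counts were summed per library and expressed as CPM. The log2 ratio of knockout over control used a pseudocount of 0.5 UMI, with the exact conditional 95% interval of a ratio of 2 counts. Poisson intervals were used for sums and Clopper-Pearson intervals for shares. A gene was named when it was among the 10 highest or the 10 lowest log2 ratios with at least 100 UMIs over both libraries, its interval excluded no difference, and no single nucleus held over 20% of its UMIs in the higher library. Zfp362, mitochondrial, antigen receptor and sex-linked genes were outside that rule. Up to 2 members at either end of each gene list, and any member of the Treg, Th17, Th1 and inflammatory cytokine lists, could also be named. The limit on a single nucleus was not a condition for these members. All 26 gene lists were fixed before the data were examined. A list's value is the median log2 ratio of its members with at least 20 UMIs, with its percentile among 10000 random lists of the same size matched over 20 expression bins, and a counting interval from 1000 Poisson redraws of the members' UMIs. The share of nuclei with a UMI of a gene was taken after thinning every nucleus to 1000 UMIs, leaving out shallower nuclei.

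Peaks were compared where a peak of one library overlapped a peak of the other by at least 1 base, which held for 87.7% of control and 85.8% of knockout peaks, and were summed within 50 kb of each gene. Peak positions are 1-based and on mm10, and exons were taken from the GENCODE vM21 annotation of that assembly. Fold and list computations were tested on Poisson counts simulated at the real depths. The intervals assume the same model, so variation between nuclei or libraries was not tested. Genes with a simulated difference were drawn from 9016 T-lineage, 3829 Treg-like and 8618 other T-lineage genes. At an absolute log2 ratio of 1, 97.1% of 69, 98.6% of 72 and 98.3% of 58 such genes were recovered. At 0.5 these shares were 75.8% of 62, 73.5% of 68 and 84.6% of 78. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

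Alternatives planned before the data were examined were edgeR 4.0.16 TMM and DESeq2 1.42.0 size factors for scaling, equal weight per nucleus, thinning, a stricter filter (1000 UMIs, 600 genes, 5% mitochondrial), all deposited barcodes, other count minimums, summed CPM, knockout clusters reweighted to the control shares, other clustering settings, other UMI rules and other peak windows and overlaps. Leaving out the mixed clusters, also from the denominator of shares, removing the marked doublets, UMAP weights, the same alternatives for single genes of Treg-like and other T-lineage nuclei, and those for Zbtb16 were added after the data had been seen. Values of some single genes and loci are not reported here, though the genes stayed in the clustering and in their lists. Barcode sequences were not used.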

Results

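Single-nucleus RNA and chromatin accessibility were profiled in the same nuclei from intestinal CD4+ effector T cells of mice with and without a conditional deletion of Zfp362, a gene for a C2H2 zinc-finger protein. The question, as the series title states it, concerns inflammatory responses of T cells and whether they depend on the differentiation of Th17 cells, the helper T cells that make IL-17. The control library came from Zfp362flox/flox mice and the knockout library from CD4creZfp362flox/flox mice, in which the Cre recombinase is driven by Cd4 regulatory sequence. Colon and small intestine were pooled, and CD4+CD44+CD62L- cells lacking CD8a, CD11c, CD45R and F4/80 were sorted. Each genotype had 1 library, with 4223 control and 2391 knockout barcodes, 10803590 and 9348999 RNA molecules counted by unique molecular identifier (UMI), and 31497489 and 34555016 counts in accessibility peaks. The median deposited barcode held 1996 and 2270 UMIs, and 4176 and 2346 nuclei remained after filtering. No replicate check exists, no test across samples was possible, and every interval below is a 95% interval that covers counting error only. RNA values are counts per 1000000 UMIs (CPM), peak values are counts per 1000000 counts in peaks shared by both libraries (peak CPM), and each log2 ratio is knockout over control.

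The 20 joint clusters contained 13 T-lineage clusters, with 3007 control and 1655 knockout nuclei, and 4 clusters low in Cd3 transcripts whose markers were those of innate lymphoid cells (ILC). These CD3-low clusters, numbers 2, 6, 10 and 13, held 25.6% (24.3 to 27.0) of the kept control nuclei and 26.4% (24.6 to 28.2) of the kept knockout nuclei although the sort selected CD4+ cells. They serve below as nuclei of the same libraries outside the T lineage. The unnamed T-lineage clusters 4 and 11 had more than 2 times the median depth and were kept apart as mixed high-UMI clusters. Together they supplied 30.8% of T-lineage UMIs in the control and 60.1% in the knockout library, so the values without them are given beside many of the results. The median T-lineage depth was 2025 UMIs in the control and 2495 in the knockout library, and 1907.5 and 2062 without the mixed clusters.

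Zfp362 itself (ENSMUSG00000028799) had few UMIs in T-lineage nuclei of either library, 78 in the control and 50 in the knockout, or 9.59 (7.58 to 11.97) and 6.72 (4.99 to 8.87) CPM. The log2 ratio was -0.51 (-1.05 to 0.02), and -0.39 (-1.18 to 0.31) without the mixed clusters, so a lower RNA level was not detectable at this depth. The labels do not state which exons the deletion removes, and nuclear UMIs from the rest of the gene would remain, so this RNA value does not check the genotype labels. CD3-low nuclei held 15 control and 4 knockout UMIs. Zfp384, its closest relative, had 206 and 217 UMIs (log2 ratio 0.20, -0.08 to 0.49). Of the neighbouring genes, Phc2 (-0.07) and A3galt2 (-0.28) had intervals that included 0.

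Peak counts at Zfp362 were lower in the knockout library's T-lineage nuclei at some peaks inside the gene. The labels do not state which part of the gene the deletion removes. Counts lost with deleted DNA therefore cannot be told apart from lower accessibility. The gene lies on the minus strand of chromosome 4 from 128773088 to 128806045 (mm10). At the intronic peak from 128784716 to 128785628, T-lineage nuclei had 15.1 peak CPM in the control and 4.71 in the knockout library, a log2 ratio of -1.68 (-2.18 to -1.31), and -2.38 (-3.37 to -1.71) without the mixed clusters. The same peak had 12.4 and 12.7 in CD3-low nuclei (log2 ratio 0.04, -0.65 to 0.62). The neighbouring intronic peak from 128788112 to 128789030 had 5.35 and 2.58 in T-lineage nuclei, and its log2 ratio without the mixed clusters was -2.97 (-5.47 to -1.48), against 0.20 (-0.51 to 0.95) in CD3-low nuclei. A further intronic stretch, from 128793576 to 128794622, held 2 called peaks in the control library and 1 in the knockout library. Its log2 ratio was -0.53 (-1.31 to 0.18) in T-lineage nuclei but -1.73 (-3.47 to -0.58) in CD3-low nuclei, on 44 and 11 counts. The unequal peak calls may enter both values. Between the first pair, a peak overlapping an exon, from 128787022 to 128787818, had 9.91 in control T-lineage nuclei, while the knockout library had no called peak overlapping it. The promoter peak from 128805728 to 128806628 had 32.4 and 30.5 (-0.08, -0.30 to 0.10). Just upstream, a peak from 128806742 to 128807328 was called in the control library alone, at 10.8 in T-lineage and 14.6 in CD3-low nuclei, and the peak from 128811129 to 128812041 was at -0.19 (-0.39 to 0.03), and at -0.33 (-0.64 to -0.02) without the mixed clusters. Over all shared peaks within 50 kb of the gene the log2 ratio was -0.34 (-0.46 to -0.23) in T-lineage nuclei, -0.51 without the mixed clusters and -0.16 within 100 kb in place of 50, and within 50 kb it was -0.77 (-1.12 to -0.44) in Treg-like nuclei and -0.11 (-0.34 to 0.08) in CD3-low nuclei. Peak intervals were computed on fragments, because most peak values were even.

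**Figure D1:**
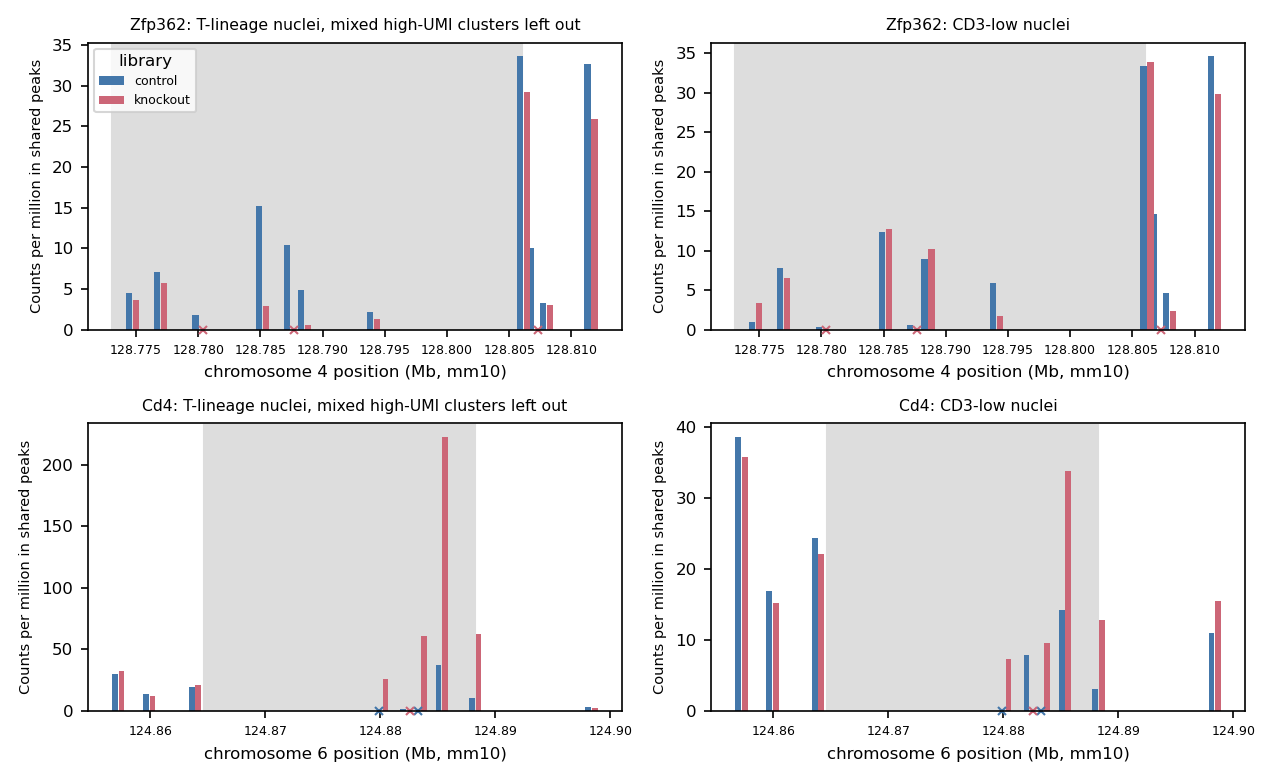
Accessibility per peak, in peak CPM, along Zfp362 (chromosome 4) and Cd4 (chromosome 6) for control and knockout libraries, in T-lineage nuclei without the mixed high-UMI clusters and in CD3-low nuclei. Grey marks the gene body, a cross marks a library with no overlapping peak, and the y scale differs between panels. The Zfp362 intronic peak at 128784716 stood at 15.2 in control and 2.89 in knockout T-lineage nuclei.

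Cd4, which encodes the co-receptor used in the sort, was higher in the knockout library's T-lineage nuclei. They had 2033 control and 5410 knockout UMIs, or 250 and 728 CPM, a log2 ratio of 1.54 (1.47 to 1.62), 1.69 (1.59 to 1.78) without the mixed clusters and 2.02 (1.82 to 2.23) in Treg-like nuclei. In CD3-low nuclei Cd4 was at 680 and 437 UMIs, a log2 ratio of 0.01 (-0.17 to 0.18). The Cd4 gene lies on the minus strand of chromosome 6 from 124864692 to 124888221 (mm10). Its peak from 124884880 to 124885797, inside an intron, had 32.6 peak CPM in control and 179 in knockout T-lineage nuclei. The peak at its promoter, from 124887804 to 124888709, had 9.10 and 49.9. Peaks from 124879727 to 124880599 and from 124883056 to 124883980, at 21.9 and 51.9, were called in the knockout library alone, and a peak from 124881819 to 124882755 in the control library alone, at 2.81 in T-lineage and 7.86 in CD3-low nuclei. The intronic peak and the promoter peak, each called in both libraries, together had a log2 ratio of 2.46 (2.29 to 2.57) in T-lineage nuclei and 1.43 (1.00 to 1.85) in CD3-low nuclei. Peaks outside Cd4 within 10 kb had 0.10 (-0.04 to 0.23) and -0.04 in those nuclei. Only the knockout mice carried the CD4cre transgene, per the labels.

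Among T-lineage nuclei, the genes with the largest positive log2 ratios after fixed minimums on counts were Tff2 (1.85, 1.52 to 2.21), Muc6 (1.78, 1.19 to 2.44), Cd4, Cd200r2 (1.52, 0.91 to 2.21), Timp3 (1.39), Nlrp3 (1.38), Spink13 (1.36), Dok6 (1.33), Khdrbs3 (1.25) and Phkg1 (1.24). Tff2 and Muc6, products of mucous gland epithelium, stood at 11.4 and 41.4 CPM and at 3.69 and 12.8 CPM, and Tff2 was higher in CD3-low nuclei too (2.50, 1.71 to 3.43). Muc6 also led stromal or endothelial cluster 20, outside the T lineage, in which epithelial markers were up as well. That cluster held 7 control and 12 knockout nuclei, 0.168% and 0.512% of those kept. Whether RNA of such cells reached T-lineage nuclei was not tested, so expression by T cells is not read from these genes. Without the mixed clusters Nlrp3, the inflammasome sensor, was at 0.30 (-1.34 to 1.77), Timp3 at 0.44 (-3.25 to 3.46) and Dok6 at -0.37 (-2.30 to 1.12), while Cd200r2 was at 1.43 (0.58 to 2.31) and Khdrbs3 at 1.99 (0.42 to 3.94). With knockout clusters reweighted to the control library's cluster shares, Spink13 was at 0.87, Nlrp3 at 0.67, Khdrbs3 at 0.55, Timp3 at 0.51 and Dok6 at 0.43, and thinned to 1000 UMIs per nucleus Muc6 was at 3.23, Spink13 at 2.33 and Khdrbs3 at 1.89. Spink13 is a leading gene of cluster 12, whose other leading genes included the heat-shock genes Hspa1a, Hspa1b and Hsph1.

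The largest negative log2 ratios in T-lineage nuclei belonged to Eomes, the T-box factor of cytotoxic and memory cells (-2.19, -2.95 to -1.55), Csgalnact1 (-1.98, -2.79 to -1.29), Slc24a3 (-1.22), St8sia6 (-1.21), Pparg (-1.13), the annexin gene Anxa1 (-1.12), Lsm2 (-1.06), Gm15503 (-1.02), Pop7 (-1.01) and Mlf1 (-1.003). Eomes stood at 13.8 and 2.96 CPM, and Csgalnact1 at 10.8 and 2.69 CPM. Without the mixed clusters Eomes was at -1.69 (-2.66 to -0.91), Csgalnact1 at -2.13 (-3.47 to -1.15), Pparg, a lipid-responsive nuclear receptor, at -1.05 (-1.70 to -0.48), Pop7 at -0.66 (-1.27 to -0.11) and Lsm2 at -0.38 (-1.12 to 0.28). Reweighted in the same way, Eomes was at -1.10, Pop7 at -0.65 and St8sia6 at -0.09, and thinned to 1000 UMIs Eomes was at -1.15, Lsm2 at -0.56 and Anxa1 at -0.32. These rankings depended on the count minimum, since at 20 UMIs in place of 100 0 of the 10 highest and 2 of the 10 lowest remained.

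The Th17 list had a median log2 ratio of 0.21 (0.15 to 0.26) in T-lineage nuclei, at percentile 99.98 of random lists matched on expression, with 14 of 20 measured members higher in the knockout library. Il17a was at 0.56 (0.32 to 0.79), Il22 at 0.67 (0.61 to 0.73), Il23r at 0.40 (0.31 to 0.48) and the homing receptor Ccr6 at 0.46 (0.27 to 0.65). The chemokine gene Ccl20 went the other way, from 110 to 30 UMIs (-1.73, -2.38 to -1.15). Ccl20 was also a leading gene of Treg-like cluster 8, with 269 control and 110 knockout nuclei. Without the mixed clusters the list's median was 0.07 (-0.02 to 0.17), at percentile 86.1, with Il17a at 0.16 (-0.20 to 0.50), Il23r at 0.08 and Il22 at 0.43 (0.17 to 0.68). Il17a was a leading gene of mixed cluster 11, so leaving that cluster out also takes away Il17a UMIs. With knockout clusters reweighted to the control shares the median was -0.01. In T-lineage nuclei outside Treg-like clusters it was 0.16 (0.10 to 0.24), and 0.13 without the mixed clusters.

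Of the mixed clusters, cluster 4 carried ILC transcripts as well as Cd3 transcripts. At 1000 UMIs per nucleus, 20.3% (17.3 to 23.4) of the nuclei of cluster 4 had a UMI of both marker groups, against 2.02% (1.58 to 2.53) of other T-lineage nuclei and 3.18% (2.38 to 4.15) of CD3-low nuclei. The ILC markers counted were Kit, Il1r1, Ncr1 and Arg1, and Il1r1 is on the Th17 list too. Cluster 11, with Il17a and Il1rl1 among its leading genes, had 2.87% (0.94 to 6.58), near those other nuclei. Cluster 11 held 75 nuclei, 1.80% (1.42 to 2.25), of the kept control nuclei and 99, 4.22% (3.44 to 5.11), of the kept knockout nuclei. Results without the mixed clusters leave it out along with cluster 4.

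**Figure D2:**
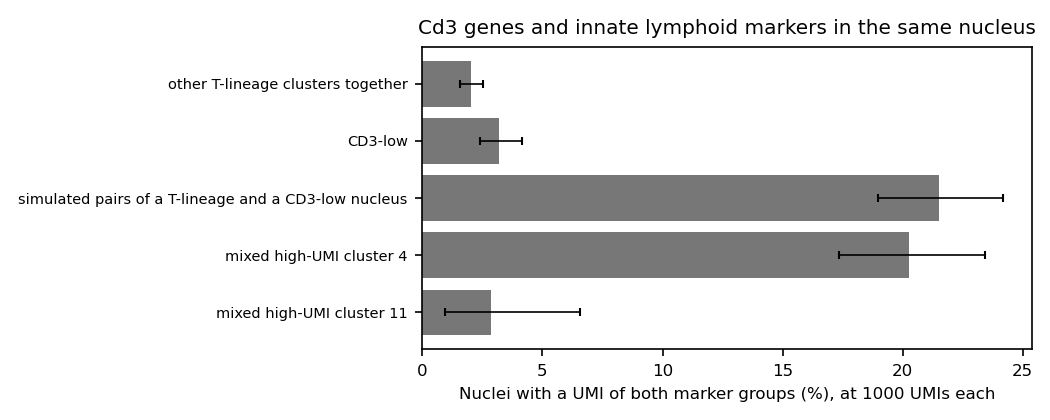
Share of nuclei, in percent, with at least 1 UMI of both Cd3 genes and ILC marker genes (Kit, Il1r1, Ncr1 and Arg1) after thinning to 1000 UMIs, with exact 95% binomial intervals, for groups of clusters over both libraries and for simulated pairs of a T-lineage and a CD3-low nucleus. Cluster 4 stands at 20.3% and the simulated pairs at 21.5%.

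Inflammatory cytokine genes went both ways. Their list had a median of 0.11 (-0.06 to 0.22) in T-lineage nuclei, with 11 of 18 members higher, and 0.02 without the mixed clusters, -0.10 with clusters reweighted and -0.07 with nuclei thinned to 1000 UMIs. Csf2, which encodes GM-CSF, was higher at 24.0 and 47.2 CPM (0.98, 0.72 to 1.24), and at 1.03 (0.63 to 1.42) without the mixed clusters. Ifng was at 123 and 109 CPM (-0.17, -0.31 to -0.04), Tnf at 0.04 (-0.15 to 0.22), Il4 at -0.70 (-0.91 to -0.49) and Il5 at 0.42 (0.00 to 0.83), and the last pair stood at -0.44 (-0.75 to -0.15) and 0.82 (0.36 to 1.27) without the mixed clusters. Counting intervals take UMIs as independent and are too narrow where few nuclei hold most UMIs of a gene. The pathogenic Th17 list had a median of 0.09 (0.03 to 0.16), inside its random range of -0.13 to 0.14, and -0.03 with clusters reweighted.

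The Th1 list, of the helper cells that make interferon-gamma, had a median of 0.06 (0.00 to 0.11) with 13 of 20 members higher, inside its random range of -0.11 to 0.12, and 0.07 (-0.03 to 0.12) without the mixed clusters. Il12rb2, an IL-12 receptor chain, stood at 406 and 561 CPM (0.46, 0.40 to 0.53), and was at 0.45 (0.37 to 0.54) without the mixed clusters. The chemokine genes split, with Ccl4 at 0.83 (0.61 to 1.05) and Ccl3 at 0.74 (0.27 to 1.23) against Ccl5 at -0.54 (-0.63 to -0.45). How many T-lineage nuclei held these chemokine UMIs was not counted, so these intervals may be too narrow. Tbx21 was at 0.18 (0.03 to 0.34). In T-lineage nuclei outside the mixed clusters Ccl3 was at 1.16, Ccl5 at -0.28 (-0.39 to -0.17) and Tbx21 at 0.09 (-0.12 to 0.29). In CD3-low nuclei the same list had a median of 0.44.

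Genes of suppressive function, of the Foxp3+ Treg lineage, were mostly lower over all T-lineage nuclei, while Treg identity genes and intestinal Treg genes went both ways. The suppressive function list had a median of -0.31 (-0.33 to -0.20) with 18 of 21 members lower, below all 10000 random lists, and -0.12 (-0.24 to -0.06) without the mixed clusters. Its members Lgals1 (-0.62), Fgl2 (-0.58), Areg (-0.43), Tgfb1 (-0.39) and Il10 (-0.24, -0.33 to -0.15) were lower, but without the mixed clusters Lgals1 was at -0.32 (-0.46 to -0.18) and Il10 at -0.04 (-0.15 to 0.08). The Treg identity list had a median of -0.13 (-0.20 to -0.07) with 12 of 20 members lower and 8 higher, and -0.11 (-0.16 to -0.02) without the mixed clusters, inside its random range of -0.12 to 0.12 there. Foxp3 stood at 73.3 and 51.1 CPM (-0.52, -0.71 to -0.33), and at -0.37 (-0.63 to -0.12) without the mixed clusters. Izumo1r was at -0.57, but at -0.26 (-0.47 to -0.05) without them, and Tnfrsf4 at -0.45, whereas Ikzf2 was at 0.18 (0.14 to 0.22). With clusters reweighted the medians of suppressive function and identity were -0.08 and -0.04. The intestinal Treg list was at 0.13 (-0.01 to 0.19), with 7 of 13 members higher.

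Within Treg-like nuclei, 777 control and 341 knockout, those lists lay near 0. Identity had a median of 0.03 (-0.07 to 0.10) and suppressive function -0.07 (-0.17 to 0.01), with Foxp3 at 223 and 205 CPM (-0.12, -0.40 to 0.15), Ctla4 at 0.03 (-0.04 to 0.10) and Il10 at 0.15 (0.03 to 0.28). Some effector molecules were lower, namely Gzmb (-0.84, -1.10 to -0.58), Fgl2 (-0.82, -1.19 to -0.47) and Tgfb1 (-0.55, -0.80 to -0.31). After Cd4, the genes with the largest positive log2 ratios were Trmt61b (1.41), the peptide transporter gene Slc15a2 (1.35, 1.06 to 1.64), Gm42031 (1.14), Plac8 (1.12), Calcrl (1.10), Pola1 (1.06), Fhit (1.01), Hspa1a (0.97) and Gm11290 (0.96). Slc15a2 was higher in CD3-low nuclei too (1.15). The largest negative ratios were those of Capn2 (-1.29, -2.20 to -0.54), Mrpl24 (-1.07), Hspb1 (-1.02), Ust (-1.0), Msrb3 (-0.99), Anp32b (-0.96), 4930444A19Rik (-0.94), Ccr7 (-0.93), Arl8b (-0.92) and Plagl1 (-0.92), but with nuclei thinned to 1000 UMIs Capn2 was at -0.52 and Anp32b at -1.63. The interferon list had a median of 0.26 (0.06 to 0.39), percentile 99.9, with 15 of 22 members higher, among them Gbp7 (0.53) and Gbp4 (0.48), but Isg15 was at -0.82 (-1.41 to -0.29). The list of T-cell receptor signalling genes, which includes Cd4, was at 0.17 (0.09 to 0.21), with Zap70 at 0.53, and that of apoptosis genes at -0.29 (-0.46 to -0.08), with Pmaip1 at -0.80 and Bax at -0.57. Co-inhibitory and exhaustion genes were at 0.20 (0.03 to 0.31), with 11 of 14 members higher, and T-cell receptor activation genes at 0.16 (0.06 to 0.26). Both lay above their random ranges, but the lists share the Nr4a genes, so the medians are not independent.

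In the other T-lineage nuclei, 2230 control and 1314 knockout, Tff2 (1.85), Muc6 (1.80), Foxj1, a forkhead factor (1.58, 0.98 to 2.25), Cd4 (1.44), Gm17103 (1.38), Cd200r2 (1.38), Spink13 (1.22), Timp3 (1.22), Phkg1 (1.22) and Nlrp3 (1.19) had the largest positive ratios. Eomes (-2.36), St8sia6 (-1.30), Lsm2 (-1.21), Pglyrp1 (-1.08), Samd4 (-1.08), Thap1 (-1.07), Cmtm4 (-1.03), Pop7 (-0.98), Slfn1 (-0.96) and Nudt16 (-0.95) had the largest negative ones. Foxj1 was at 2.06, Timp3 at 0.37, Nlrp3 at 0.04, Lsm2 at -0.45, Thap1 at -0.45, Slfn1 at -0.61, Pop7 at -0.64 and Eomes at -1.75 without the mixed clusters. Reweighting clusters gave 0.60 for Nlrp3, 0.51 for Timp3, -0.0082 for St8sia6, -0.48 for Slfn1, -0.64 for Pop7 and -1.10 for Eomes, and thinning to 1000 UMIs gave 2.99 for Muc6, 2.35 for Spink13, 1.83 for Nlrp3, -0.12 for Thap1, -1.25 for Eomes and -1.49 for Pop7. The intestinal Treg list, which shares Il17a, Il23r, Ccr6 and other genes with the Th17 list, had a median of 0.31 (0.16 to 0.36) here, 0.15 without the mixed clusters and 0.05 with clusters reweighted.

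Genes of naive and central memory T cells were lower in the knockout library's T-lineage nuclei. The list had a median of -0.47 (-0.59 to -0.31), with 11 of 13 members lower, and -0.41 (-0.59 to -0.22) without the mixed clusters. Ccr7 and S1pr1, receptors for homing to lymph nodes and leaving them, were at -0.70 (-0.85 to -0.56) and -0.56, and Klf2, their regulator, at -0.58 (-0.68 to -0.48), while Foxp1 was at 0.00, and at -0.14 (-0.21 to -0.07) without the mixed clusters. With reweighted clusters the median was -0.14. Nuclear genes of oxidative phosphorylation had a median of -0.24 (-0.35 to -0.20), with all 18 members lower, and -0.16 (-0.25 to -0.09) without the mixed clusters, but they were also at -0.37 in CD3-low nuclei. Mitochondrial transcripts made up 0.378% of T-lineage UMIs in the control and 0.197% in the knockout library.

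The remaining lists had medians between -0.16 and 0.13 in T-lineage nuclei. Cell cycle genes were at -0.16, Th2 genes at -0.15, glycolysis at -0.15, tissue-repair Treg genes at -0.13, Tfh genes at -0.12, cytotoxic genes at -0.11, apoptosis at -0.10, co-inhibitory and exhaustion genes at -0.08 and TGF-beta signalling at -0.07. Interferon response genes were at -0.0028, T-cell receptor activation genes at 0.01, IL-2 and STAT5 signalling genes at 0.02, T-cell receptor signalling genes at 0.03, dissociation stress genes at 0.04, tissue residency at 0.07, C2H2 relatives at 0.09, NF-kB genes at 0.11 and intestinal Treg genes at 0.13. With the mixed clusters left out, the medians of cell cycle (0.03), co-inhibitory (0.0046), stress (-0.04), cytotoxic (0.05), IL-2 and STAT5 (-0.07) and interferon genes (0.08) had the other sign, and that of stress genes also turned with DESeq2 size factors. T-cell receptor signalling was at 0.12 (0.02 to 0.17) and tissue-repair Treg genes at -0.05 without those clusters, both beyond the counting interval of the reported value. Clusters reweighted turned the sign of Tfh (0.01), co-inhibitory (0.04), stress (-0.15), T-cell receptor activation (-0.08), tissue residency (-0.0090) and IL-2 and STAT5 genes (-0.03). Tissue-repair Treg genes were at 0.0026 when nuclei were thinned and at 0.10 as summed CPM, by which intestinal Treg genes were at -0.05 and tissue residency at -0.04, and thinned interferon genes were at 0.12. T-cell receptor signalling was at -0.01 with DESeq2 size factors and at -0.04 with equal weight per nucleus. Of these lists, Th2, glycolysis, apoptosis, TGF-beta, C2H2 and NF-kB medians had the same sign under every alternative run.

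**Figure D3:**
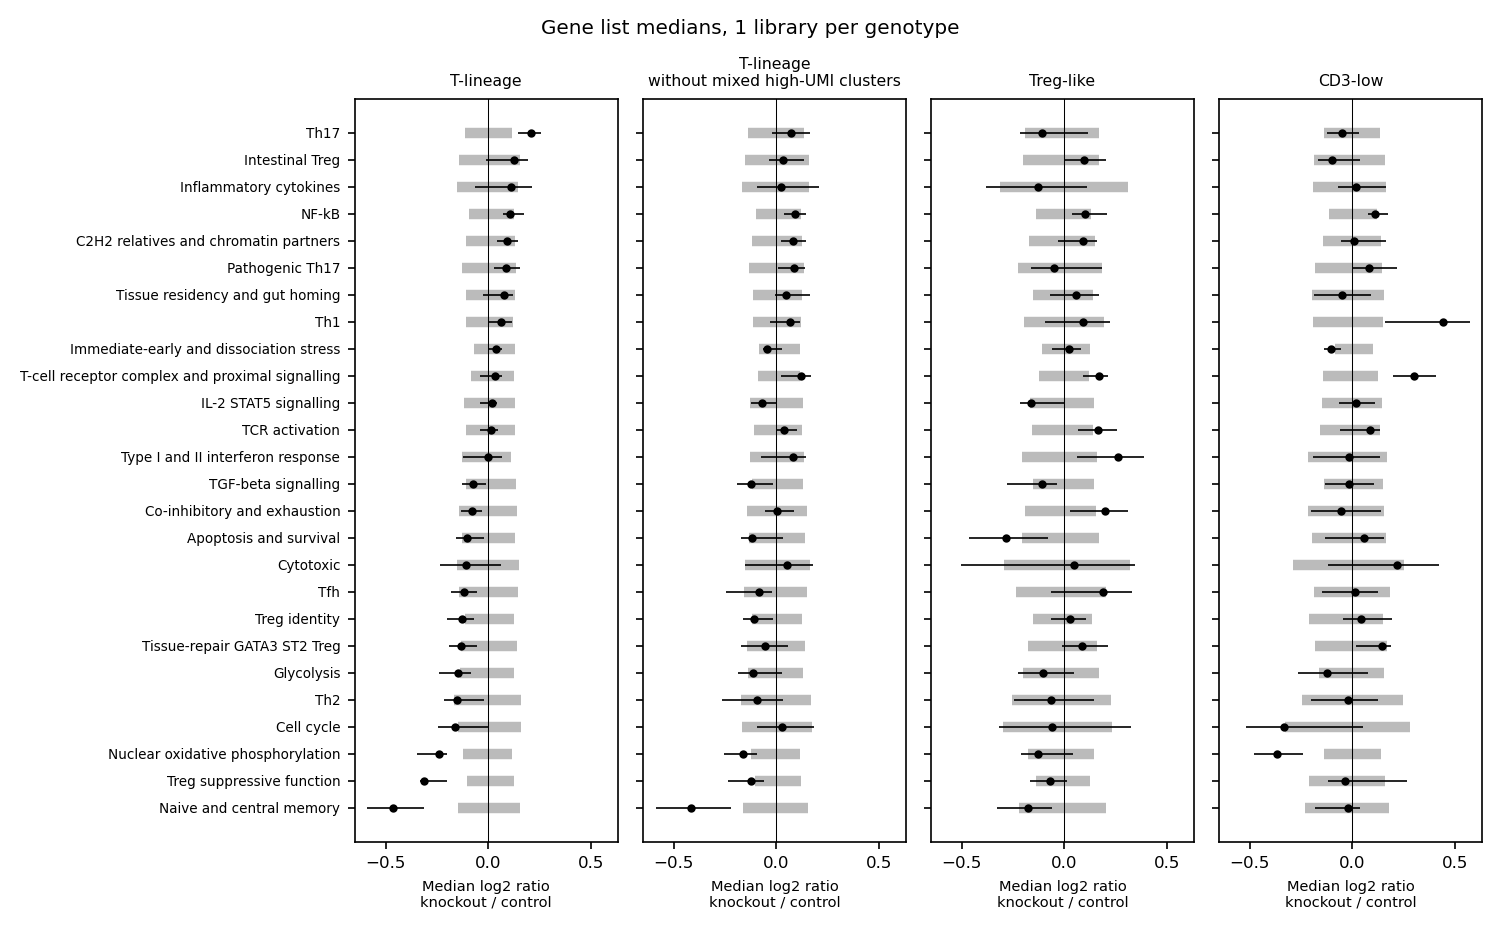
Median log2 ratio, knockout over control, of the fixed gene lists in 4 populations of nuclei, as points with their 95% counting intervals. Grey bars span the central 95% of 10000 random lists matched on expression. In T-lineage nuclei the naive list lies at -0.47 and the Th17 list at 0.21, and the Th17 list lies at 0.07 without the mixed clusters.

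No cluster of the reported clustering met the naming criteria for Th17-like cells, whose thresholds were set after the data had been seen. When nuclei were thinned to 1000 UMIs before clustering, 1 cluster met the marker counts, with Il17a, Il17f, Il22 and Il1r1 up. Il1r1 is also on the ILC list, and the ILC marker Tnfsf11 and the gamma-delta T-cell markers Tcrg-C1 and Cd163l1 were up as well. The leading genes of this cluster included Palld, Fstl4 and Prim1, which also led CD3-low cluster 13. It is therefore not read as Th17-like cells, though T cells that express Il17a within it stay open. It held 12.6% (11.4 to 13.8) of control and 18.0% (16.2 to 20.0) of knockout T-lineage nuclei. Of its nuclei, 68.8% in the control and 83.2% in the knockout library belonged to the mixed high-UMI clusters, and 29.3% and 15.5% to the CD3-low clusters, of the reported clustering. Treg-like clusters 3 and 8 held 25.8% (24.3 to 27.4) of T-lineage nuclei in the control and 20.6% (18.7 to 22.6) in the knockout library, and Tfh-like cluster 7 held 13.3% (12.1 to 14.5) and 7.13% (5.94 to 8.48). Th1-like clusters 1, 12 and 17 held 22.0% (20.6 to 23.6) and 26.2% (24.1 to 28.4), and the clusters went different ways, with 537, 59 and 67 control against 322, 96 and 16 knockout nuclei. Spink13 and heat-shock genes led cluster 12 and Eomes led cluster 17, and these genes differed between the libraries, so the sizes of those clusters are not read by themselves. The Th1-like difference of 4.18 percentage points was 1.14 at Leiden resolution 1.5, where the class held 11.6% and 12.7%, and 10.7 with the mixed clusters out of the denominator. Th2-like cluster 9 held 5.95% and 4.77%, cytotoxic cluster 15 1.86% and 3.02%, cycling cluster 18 0.898% and 0.785%, and the unnamed cluster 5, led by Lgals3 and Crip1, 13.6% and 9.18%. Mixed high-UMI clusters held 13.7% (12.5 to 15.0) and 27.7% (25.6 to 30.0). Cluster 4 had a median depth of 4567.5 and 6986.5 UMIs, against 4283 and 5599 in the small cycling cluster 18, and the size of the mixed clusters lowers every other share. The Treg-like difference was -5.24 percentage points, and -1.44 with the mixed clusters out of the denominator. Under a stricter filter on nuclei it was 0.622, but the class was then a smaller one, at 11.9% and 12.6%. The difference stayed negative under every other setting run, so its direction depended on the processing in that setting alone. Under 5 settings (30 neighbours, 1000 or a larger number of variable genes, UMAP weights, and thinning) the Treg-like class was far smaller, at 8.18% to 8.72% in the control and 5.54% to 5.77% in the knockout library, so differences in points under those settings are of a smaller class. The Tfh-like difference of -6.14 points was -4.03 with 1000 variable genes, where the class held 7.83% and 3.7998%. Naive-like shares are plotted but not read as a difference in size, because the leading genes of cluster 16 had a median log2 ratio of -0.50 over all nuclei and -0.43 in T-lineage nuclei outside the cluster, against 0.15 inside it.

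**Figure D4:**
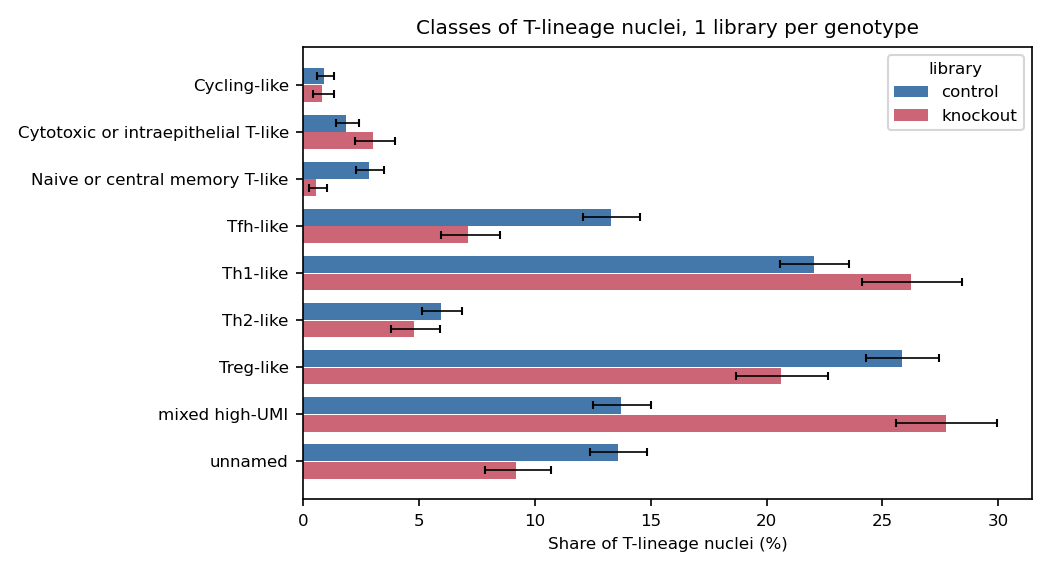
Share of T-lineage nuclei in each class of clusters, in percent, for the control and knockout libraries, with exact 95% binomial intervals. The mixed high-UMI clusters hold 13.7% of control and 27.7% of knockout nuclei, and Treg-like clusters 25.8% and 20.6%.

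Counting nuclei with at least 1 UMI of a gene, after thinning each to 1000 UMIs, gave Foxp3 in 6.45% (5.58 to 7.40) of control and 4.90% (3.89 to 6.08) of knockout T-lineage nuclei, against 0.0967% and 0.166% of CD3-low nuclei. Il17a was seen in 1.52% (1.10 to 2.03) and 2.32% (1.64 to 3.19), against 1.06% (0.53 to 1.90) and 0.666% (0.18 to 1.70) in CD3-low nuclei, so the control share lay within the range of that background. The Il17a difference of 0.807 percentage points was 0.435 without the mixed clusters. Ifng was in 7.90% and 7.60%, against 1.06% and 0.666%, Tbx21 in 7.69% and 8.48%, against 1.16% and 1.83%, and Il10 in 12% and 10.6%, against 0.870% and 0.998%. Ctla4 was in 55.6% and 56.7%, against 3.87% and 5.32%, an order opposite to its CPM (-0.13) and therefore not read. Gata3 was in 23.8% and 23.9% and Ikzf2 in 46.7% and 51.1%, and CD3-low nuclei held both genes as well (12.2% and 8.15%, and 34.5% and 35.9%). Thinning left out 107 control and 63 knockout T-lineage nuclei, and median depths before it were 2025 and 2495 UMIs in T-lineage and 1956 and 2044 in CD3-low nuclei.

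Without thinning, the T-lineage shares were 13.7% and 14.8% for Foxp3, an order opposite to its CPM, 2.49% and 5.26% for Il17a, 13.9% and 20.7% for Ifng, 14.2% and 21.8% for Tbx21, 17.0% and 18.9% for Il10, 70.0% and 74.7% for Ctla4, 38.1% and 45.5% for Gata3 and 56.9% and 66.2% for Ikzf2. Il22 was in 7.97% and 12.8% of thinned T-lineage nuclei (12.6% and 22.2% unthinned), Il23r in 11.4% and 16.0% (19.3% and 30.5%), Il2ra in 16.9% and 20.3% (30.2% and 39.7%), Ccr6 in 3.17% and 5.21% (9.28% and 17.2%) and Il17f in 0.862% and 1.82% (2.66% and 5.80%). CD3-low nuclei had higher shares of those 5 genes, with Il22 in 50.6% and 49.1%, and no measured population lacked them, so no background could be set and these shares are not read as expression by T cells. Without the mixed clusters Il22 was in 3.14% and 3.44% and Il23r in 6.27% and 7.14%.

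Accessibility around Il17a and Il23r was higher in the knockout library's T-lineage nuclei, and that around Ccr6, of the same Th17 list, was at -0.02 (-0.10 to 0.05). Over all nuclei without a filter, which include the CD3-low nuclei, Il17a was at -0.02 and Il23r at 0.015. In T-lineage nuclei shared peaks within 50 kb had log2 ratios of 0.28 (0.13 to 0.44) at Il17a and 0.27 (0.13 to 0.41) at Il23r. With the mixed clusters left out these were 0.29 (0.02 to 0.51) and 0.23 (0.01 to 0.44), and in CD3-low nuclei -0.21 and -0.16. Levels were higher in control CD3-low nuclei, at 156 and 181 peak CPM, than in control T-lineage nuclei, at 51.0 and 63.0. A different amount of ILC material among T-lineage nuclei therefore stays open for both loci. Ctla4 was at -0.18 (-0.25 to -0.11), Ifng at -0.18 (-0.29 to -0.09), Il10 at -0.16 (-0.25 to -0.09), Bcl6 at -0.13, Foxp3 at -0.09, Gata3 at -0.09, Cd3e at -0.08, Il2ra at -0.04, Ikzf2 at 0.02, Tbx21 at 0.03 and Tcf7 at 0.04. In Treg-like nuclei Gata3 was at -0.37 (-0.58 to -0.14) and Foxp3 at -0.17 (-0.40 to 0.00). The Cd4 region as a whole was at 0.71 (0.65 to 0.76). Within 10 kb Ifng was at 0.04. Foxp3 was at -0.0041, Il10 at -0.08 and Gata3 at -0.20 without the mixed clusters.

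Some RNA differed between the libraries in every population. Mitochondrial transcripts had log2 ratios of -0.94 (-0.97 to -0.91) in T-lineage and -0.85 (-0.93 to -0.77) in CD3-low nuclei. Immunoglobulin transcripts, made by plasma cells, took 0.0222% of T-lineage UMIs in the control and 0.138% in the knockout library (2.64, 2.57 to 2.71), and were at 0.99 (0.81 to 1.18) in CD3-low nuclei. Across 4927 genes the log2 ratios of T-lineage and CD3-low nuclei had a Pearson correlation of 0.35, taken across genes, which are not independent replicates. The median log2 ratio of the 9016 T-lineage genes with at least 100 UMIs was 0.00.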

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

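The tests of Cd4 and of mitochondrial RNA were chosen only after those results had been seen, while the tests of the mixed clusters were written before they were run, when the clusters' leading genes and depths were already known.

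Some signals stood above the control in CD3-low nuclei, which lie outside the main comparisons of T cells. In those nuclei Tff2 had a log2 ratio of 2.50 (1.71 to 3.43), on 16 control and 59 knockout UMIs. Slc15a2 was at 1.15 (0.90 to 1.41). The list of T-cell receptor signalling genes had a median of 0.30 (0.20 to 0.41) there, with 20 of 22 members higher. The peaks inside Cd4 were at 1.43 (1.00 to 1.85).

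Cd4 RNA and accessibility inside Cd4 were higher in the knockout library's T-lineage nuclei. For the RNA, a shift of the whole library is argued against by Cd4 RNA in CD3-low nuclei, at 0.010 (-0.17 to 0.18), below the T-lineage interval of 1.47 to 1.62. That value does not bear on the peaks. Extra copies of Cd4 regulatory DNA brought by the CD4cre transgene may account for the peaks, since those inside Cd4 were at 1.43 in CD3-low nuclei as well, while peaks outside the gene within 10 kb were at 0.10 in T-lineage nuclei. That test leaves T-cell material in CD3-low nuclei open, because their T-cell receptor list was also higher. An effect of the deletion on the endogenous Cd4 gene, with RNA at 1.54 in T-lineage nuclei, cannot be told apart from the transgene, as both occur in the same single library.

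Mitochondrial RNA was lower in the knockout library's T-lineage nuclei. Its log2 ratio in CD3-low nuclei was -0.85 (-0.93 to -0.77), which argues against an effect of genotype limited to T-lineage nuclei. A candidate explanation is nuclei preparation or free RNA that differed between the libraries, which needs the lower value in both populations. A difference between the animals that reaches every cell type stays open and was not tested.

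The mixed high-UMI clusters were larger in the knockout library. In cluster 4, 20.3% (17.3 to 23.4) of nuclei at 1000 UMIs had both Cd3 and ILC transcripts. This was near the 21.5% of simulated pairs and above other T-lineage (2.02%) and CD3-low nuclei (3.18%). Droplets with a T and an ILC nucleus may therefore make up much of cluster 4. Its share was 22.8% in the control and 17.9% in the knockout library. Single T nuclei with Il1r1, also a Th17 list gene, would count as both, so they stay open. Simulated pairs were thinned as well, so depth was not compared. The median of cluster 4 in the knockout library was 6986.5 UMIs, against 2062 in T-lineage nuclei outside the mixed clusters and 2044 in CD3-low nuclei. Cluster 11 had 2.87% (0.94 to 6.58), which leaves its origin open, since pairs of T nuclei would not show in this measure. An effect of the genotype on the size of these clusters stays open and was not tested.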

How the results depend on the processing

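Leaving the mixed clusters out, removing marked doublets, UMAP weights, the alternatives for single genes of Treg-like and other T-lineage nuclei and those for Zbtb16 were chosen after the data had been seen, and all other alternatives were planned. Of 1639 values recomputed under an alternative, 1414 stayed within the counting interval of the reported value, 197 moved beyond it, and 28 whose reported interval excluded 0 changed sign. Counting values whose reported interval included 0 as well, 128 had the other sign, 30 of them among the 197. No value moved with edgeR TMM factors, members at 1 or 100 UMIs, marked doublets removed, 50 components, seed 1, thinning to 1500 UMIs or scaling to all peaks. Leaving out a replicate was not possible with 1 library per genotype, and keeping doublets was the reported setting. No paired analysis was possible because each genotype had 1 library and the results come from no test. Some classes were absent under a setting: cytotoxic with 1000 variable genes, Tfh at resolution 0.5, and cytotoxic, naive and mixed when thinned before clustering. At 20 or 300 UMIs the genes ranked highest and lowest were mostly others. The cause was not tested for any value below. Depth limits genes such as Zfp362, with 78 and 50 UMIs.

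With the mixed clusters left out (T-lineage unless stated), Dok6 was at -0.37, and list medians were -0.12 for Treg suppressive function, 0.072 for Th17, 0.0046 for co-inhibitory, -0.044 for stress and 0.028 for cell cycle genes. In other T-lineage nuclei they were -0.093 for Treg identity, -0.11 for tissue-repair Treg, 0.17 for cytotoxic and 0.0046 for cell cycle genes. Differences in the share of nuclei with a UMI (knockout minus control, percentage points, here and below) were 0.300 for Il22, 0.177 for Il2ra and 0.864 for Il23r. Accessibility was -0.51 at Zfp362, -0.0041 at Foxp3, -0.081 at Il10, -0.20 at Gata3 and 0.85 at Cd4.

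With clusters reweighted, T-lineage medians were -0.044 for Treg identity, -0.077 for suppressive function, -0.011 for Th17, -0.032 for pathogenic Th17, 0.013 for Tfh, 0.037 for co-inhibitory, -0.15 for stress and -0.10 for cytokine genes. In other T-lineage nuclei tissue-repair Treg was at -0.15, Th17 at -0.031 and pathogenic Th17 at -0.13. With equal weight per nucleus Treg identity was at -0.038, suppressive function at -0.20 and Th17 in other T-lineage nuclei at 0.25. As summed CPM, T-lineage Treg identity was at -0.041, suppressive function at -0.18 and tissue-repair Treg at 0.10. In Treg-like nuclei Treg identity was then at 0.11 and Th17 at 0.13, and in other T-lineage nuclei they were at 0.13 and 0.26. With DESeq2 size factors suppressive function was at -0.36 and stress at -0.0068. Over all deposited barcodes, which hold other cell types too, Th17 was at -0.029 and stress at -0.032, and of the highest and lowest genes Tff2 was at 1.23, Phkg1 at 0.63, Nlrp3 at 0.60, Timp3 at 0.43, Khdrbs3 and Dok6 at 0.37, Anxa1 at -0.53, St8sia6 at -0.76 and Csgalnact1 at -1.02. Thinned to 1000 UMIs, T-lineage suppressive function was at -0.17, tissue-repair Treg at 0.0026 and cytokines at -0.067, cytokines in Treg-like nuclei at -0.60 and Th17 in other T-lineage nuclei at 0.27.

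Differences in class shares were, thinned before clustering, -2.66 for Treg-like (8.43% and 5.77%, a far smaller class) and 1.60 for unnamed clusters. At resolution 0.5 they were -7.20 for naive-like, which is not read as a difference in size, and 11.1 for mixed, and at resolution 1.5 1.14 for Th1-like and -2.38 for unnamed clusters. With 1000 variable genes they were -4.03 for Tfh-like, -2.65 for Treg-like (8.26% and 5.61%) and -9.16 for unnamed, and with a larger set of them -2.64 for Treg-like (8.18% and 5.54%) and -7.06 for unnamed clusters. Under the stricter filter they were 0.622 for Treg-like (11.9% and 12.6%), 10.8 for mixed and -7.50 for unnamed clusters. With 30 neighbours mixed was 11.4, and with UMAP weights unnamed was -8.09. Without mixed clusters in the denominator Th1-like was 10.7 and Treg-like -1.44.

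Differences in the share of nuclei with a UMI, thinned to 500, were 0.0825 for Foxp3 and 0.154 for Il17f. Without thinning, which lets the deeper knockout nuclei count more, they were 1.07 for Foxp3, 2.76 for Il17a, 3.14 for Il17f, 9.63 for Il22, 6.86 for Ifng, 7.59 for Tbx21, 7.39 for Gata3, 1.89 for Il10, 9.50 for Il2ra, 4.65 for Ctla4, 9.26 for Ikzf2, 7.88 for Ccr6 and 11.2 for Il23r. At 2 UMIs without thinning they were 0.946 for Foxp3, 1.81 for Il17a, 7.85 for Il22, 4.11 for Ifng, 4.91 for Tbx21, 7.99 for Gata3, 1.90 for Il10, 8.05 for Il2ra, 7.26 for Ctla4, 9.02 for Ikzf2, 3.93 for Ccr6 and 9.79 for Il23r.

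Accessibility within 100 kb was -0.16 at Zfp362, -0.069 at Il10 and 0.44 at Cd4. Within 10 kb it was 0.042 at Ifng, -0.20 at Il2ra, 0.15 at Tcf7, 2.32 at Cd4 and -0.15 at Cd3e. Over all nuclei it was -0.017 at Il17a, -0.088 at Ctla4, 0.015 at Il23r and 0.58 at Cd4. With reciprocal overlap of 50% it was 0.0056 at Bcl6 and 0.62 at Cd4.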

Other observations

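No test reported in this part was planned, and the genes named here were chosen after their values had been seen.

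Some genes known from T cells differed between the libraries in CD3-low nuclei, which carried ILC markers, and some of these values rested on few nuclei. The T-cell receptor list was higher there too (0.30, 0.20 to 0.41), and CD3-low cluster 10, with Ncr1 and Klrb1c among its leading genes, held 2.66% (2.19 to 3.19) of kept control and 3.75% (3.02 to 4.60) of kept knockout nuclei, so T-cell material and the mix of clusters both stay open for these values. Ccl4, a chemokine gene of activated lymphocytes, had 5 control and 78 knockout UMIs there, a log2 ratio of 4.48 (3.33 to 6.27), but the knockout UMIs lay in 6 nuclei, 31 of them in a single one, and the control UMIs in 4 nuclei. Counting intervals take UMIs as independent and are too narrow in such a case. Il12rb2 was at 0.83 (0.42 to 1.25), with 33.3% of its knockout UMIs in 1 nucleus. Areg, which encodes amphiregulin, was at 1.503 (1.06 to 1.97), opposite to its value in T-lineage nuclei (-0.43), with UMIs in 39 control and 33 knockout nuclei. Gzmb was at 1.08 (0.38 to 1.80), in 16 and 18 nuclei, and Ctla4 at 0.95 (0.66 to 1.24), in 71 and 62 nuclei. The Th1 list had a median of 0.44 (0.16 to 0.57), above its random range of -0.19 to 0.15, with 16 of 18 members higher. Tff2 and Slc15a2 were spread more widely, over 16 and 52 nuclei and over 146 and 175 nuclei. Il22, an ILC cytokine gene, was at -0.0047 (-0.06 to 0.05) on 7879 and 5014 UMIs, and Il23r at -0.09 (-0.17 to -0.01).

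Within T-lineage nuclei, Zbtb16, which encodes the factor PLZF of innate-like T cells, stood at 55.8 and 113 CPM, a log2 ratio of 1.02 (0.86 to 1.19), and at 1.02 (0.76 to 1.28) without the mixed clusters. It is a leading gene of cytotoxic cluster 15, which held 1.86% of control and 3.02% of knockout T-lineage nuclei. Its log2 ratio was 1.29 (1.09 to 1.5003) without cluster 15, 0.71 (0.21 to 1.20) without both cluster 15 and the mixed clusters, and 0.47 with clusters reweighted, so its size depended on which clusters were counted. Zbtb16 was at -0.03 in CD3-low nuclei. The heat-shock gene Hspa1a was at 0.59 (0.54 to 0.65) in T-lineage nuclei, 0.95 (0.87 to 1.02) without the mixed clusters, 0.97 (0.80 to 1.14) in Treg-like nuclei and -0.10 (-0.18 to -0.02) in CD3-low nuclei. Whether these differences come from the genotype or from the handling of a single library was not tested.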
